A study of Corynebacterium glutamicum with 6 samples.

How the data were processed

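RNA was measured in 6 libraries of Corynebacterium glutamicum ATCC13032, 3 from strain JS133, which the labels call the reference, and 3 from strain JS134, which carries a deletion of zwf in that background. Per the labels' protocols, cells were pre-grown with air, concentrated in fresh minimal medium with glucose or fructose, and deprived of oxygen by keeping dense suspensions unaerated with slow mixing; which sugar and which sampling time apply to these libraries is not given in the sources used here. Total RNA was isolated on silica columns and sequenced with the standard library protocol of a BGISEQ instrument, per the labels' protocols.

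Each deposited file holds 1 library with 2993 gene rows. Per the file headers, the authors gave the count of all reads per gene, the count of uniquely placed reads, RPKM and TPM. The deposited RPKM values equal the total count per gene divided by gene length and by the library's summed gene count, and the deposited TPM values sum to the same total in each library. The aligner, its settings, the filters and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. Coordinates are 1-based positions on the chromosome named in the files, a modified copy of the ATCC13032 chromosome.

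Gene IDs in the files matched the RefSeq gene table of assembly ASM1132v1 for 2842 of the 2993 rows, and 666 rows have a symbol from the files or that table. Rows with no symbol are named by the NCgl identifier of the files. The lpdA gene model is 1425 bp in the files and 1410 bp in the table, and 2306 of the 2499 matched genes that follow it start 15 bp later than in the table, so no coordinate of the table is printed. No matched row is a ribosomal or transfer RNA.

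The main test, fixed before the data were examined, was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the total counts as deposited, with TMM normalization, the default expression filter by strain and strain as the only term. It left 2985 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Log2 fold changes are zwf deletion minus reference, and each standard error was derived from the fold change and its F statistic. CPM values are TMM-normalized. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

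Genes were named by a rule fixed before the data were examined. It takes zwf, its neighbours and the gene for 6-phosphogluconate dehydrogenase; the 10 largest rises and the 10 largest falls among genes past the threshold whose libraries separate by strain and whose mean is at least 10 CPM; up to 4 called members of each gene list, or the member with the smallest p where none was called; and a few genes of central metabolism, of which ldh, ppc and gap have a symbol match. Before the data were examined 29 gene lists were also fixed, and 25 had a tested member. The lists for iron homeostasis, fatty acid biosynthesis, mycolic acid and cell envelope, and the CGP3 prophage had no member matched by symbol and were not analysed here. List members were counted over all genes tested and adjusted over the list alone. Lists with at least 3 tested members, 22 in all and with zwf left out, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01.

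The edgeR step was tested on simulated counts with the depths and spreads of these libraries, in 3 runs of 2985 genes with 200 changed genes each. It called 78% of genes changed 4-fold, 11% of genes changed 2-fold and 0.12% of unchanged genes. The simulated genes varied independently of each other, with as many rises as falls. A deviation shared across genes, as in reference replicate 1, was not simulated, so these rates may not hold for these data. The depth was 4547925, 1924002 and 1991246 gene reads in the reference replicates 1, 2 and 3, and 18913336, 18696714 and 16541182 in the zwf deletion replicates 1, 2 and 3. A floor of 3 reads corresponds to 0.637 to 1.45 CPM in the reference libraries and 0.17 to 0.192 CPM in the zwf deletion libraries. Intervals and floors cover counting error only.

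Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile factors, library size alone, no filter, a filter of at least 50 reads in every library of a strain, limma-voom, a test against a 2-fold change, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and the fry test. Alternatives chosen after seeing the data were unique reads only, zwf deletion libraries thinned to the mean reference depth, subtraction of a floor per gene length set at the 1st percentile of RPKM in each library, and limma-voom with sample weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.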

Results

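Transcript levels were compared between a reference strain of Corynebacterium glutamicum and its zwf deletion derivative during oxygen deprivation, with 3 RNA-seq libraries of each strain. C. glutamicum is a soil actinobacterium used in industry to make amino acids and organic acids, and zwf encodes a subunit of glucose-6-phosphate dehydrogenase, the entry enzyme of the oxidative pentose phosphate pathway. The comparison asks how expression differs with and without zwf when oxygen is short. The reference libraries held 1924002 to 4547925 gene reads and the zwf deletion libraries 16541182 to 18913336, so depth differed with strain.

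The zwf transcript was nearly lost in the deletion strain. The gene (NCgl1514, from 1667875 to 1669419 on the plus strand) had 199, 342 and 332 reads in the reference replicates and 2, 1 and 0 reads in the deletion replicates. The reference level was 120 ± 67.9 CPM (SD, n = 3) against 0.057 ± 0.0571 CPM (SD, n = 3). Over the pooled 873 and 3 reads the ratio was 1653, with a 95% exact counting interval of 564 to 8031. The edgeR quasi-likelihood test gave an adjusted p of 0.00411. Reference replicate 1 had 42.3 CPM of zwf, against 165 and 153 CPM in reference replicates 2 and 3.

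None of the 4 neighbours of zwf passed the threshold in edgeR, where pgl was the 1 gene at an unadjusted p under 0.05. Upstream, tkt (transketolase) had a log2 fold change of 0.42 and tal (transaldolase) of -0.31, with adjusted p of 0.29 and 0.513. Downstream, NCgl1515 had -0.90 and pgl (6-phosphogluconolactonase) -1.14, with adjusted p of 0.21 and 0.0514. The gndA gene for 6-phosphogluconate dehydrogenase, which lies elsewhere, had -0.26 with adjusted p of 0.569. Without reference replicate 1, tal, NCgl1515 and pgl were called lower, with log2 fold changes of -0.60, -1.33 and -1.46, while gndA stood at 0.05. The pgl gene was also called with DESeq2, upper-quartile factors and library size alone, at adjusted p of 0.0246, 0.0436 and 0.0314. In the list of the oxidative pentose phosphate pathway 1 of 3 tested members, zwf itself, was called, and adjusted over the list alone 2 were lower. Of the 4 genes fixed for that list, opcA had no match by symbol, so these counts leave it out. In the non-oxidative list edgeR called 0 of 3, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05.

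**Figure D1:**
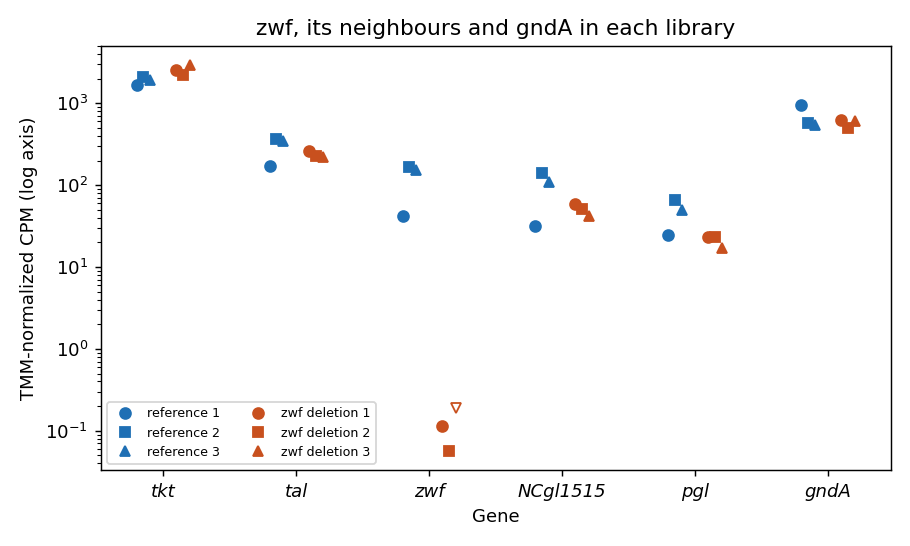
TMM-normalized CPM on a log axis of zwf, its 4 neighbours and gndA in each of the 6 libraries, with each point a library. The open triangle stands at the floor of 3 reads, 0.192 CPM, for the library with 0 zwf reads; the zwf points of the reference strain lie between 42.3 and 165 CPM.

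Beyond zwf, some genes of glycolysis and 2 of the oxidative and thiol stress list, mtr and msrA, were higher in the deletion strain, while genes of nitrate respiration, ATP synthase, iron-sulfur cluster assembly and tryptophan synthesis were lower. Of 2985 genes tested, 276 were higher and 575 were lower, and 227 and 512 of these differed at least 2-fold. The 3 libraries of each strain separated without overlap for 1481 genes, 49.6% against 10% by chance. Genes vary together and depth differed with strain, so this contrast is not a test of the strain difference. With library size alone 202 were higher and 716 lower, so the higher share of calls was 22% in place of 32.4%. The median log2 fold change over all genes was -0.08 with TMM, -0.21 with upper-quartile factors and -0.26 with library size alone. Without reference replicate 1 the counts were 926 and 965. They were 180 and 308 without reference replicate 2, and 63 and 167, 62 and 187, and 90 and 214 without zwf deletion replicate 1, 2 or 3.

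Reference replicate 1 stood apart from the other reference libraries. Across genes, its log2 CPM correlated at 0.874 and 0.836 with reference replicates 2 and 3 and at 0.909 to 0.921 with the deletion libraries; genes are not independent replicates. The biological coefficient of variation was 47.7% among the reference libraries and 13% among the deletion libraries. The edgeR test uses a single spread per gene for both strains, so its p-values pool these unequal spreads. A call that ended without a deletion library need not mean that its fold change moved.

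**Figure D2:**
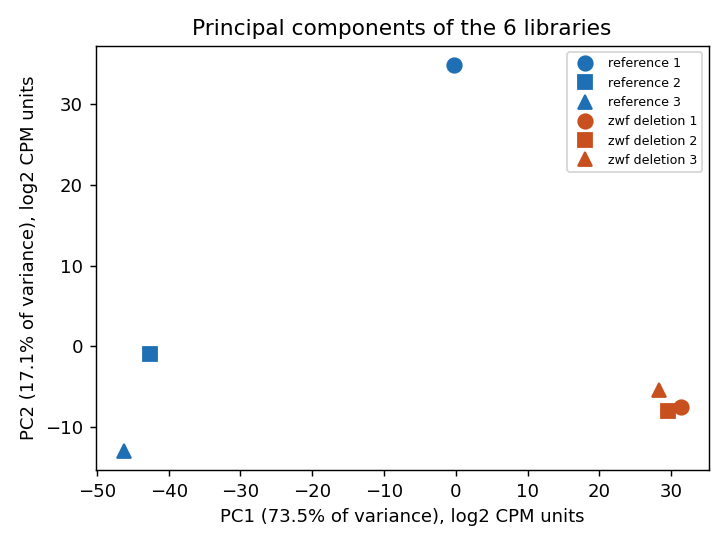
Principal components of log2 CPM over the tested genes, with each point a library. On the horizontal axis, 73.5% of the variance, reference replicate 1 lies at -0.32, the other reference libraries at -42.6 and -46.3, and the deletion libraries between 28.3 and 31.3. On the vertical axis, 17.1% of the variance, reference replicate 1 lies at 34.9 and the other libraries between -13 and -0.9.

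The largest rise in the deletion strain among genes that met the rule was in ppc, which encodes phosphoenolpyruvate carboxylase, from 17.1 ± 11.5 to 134 ± 29.5 CPM (SD, n = 3 each), a log2 fold change of 2.92 (SE 0.47, edgeR adjusted p = 0.00589). Reference replicate 1 had 30.2 CPM of ppc, against 8.7 and 12.5 CPM in reference replicates 2 and 3. The 3 genes that lie next to ppc on the minus strand also rose. These were tpiA (triosephosphate isomerase) by 1.68, pgk (phosphoglycerate kinase) by 1.98 and gap (glyceraldehyde-3-phosphate dehydrogenase) by 1.61 on the log2 scale, in the stretch from 1677399 to 1683640. Along the minus strand their order is gap, pgk, tpiA and ppc, so the rise was largest at the downstream end. The gap transcript, at 52460 ± 2580 CPM in the deletion strain, stood at 29820 CPM in reference replicate 1 and at 9430 and 12400 CPM in reference replicates 2 and 3. Of the 8 tested genes of glycolysis these 3 were higher and 5 were not called; adjusted over the list alone 4 were higher, and without reference replicate 1 all 8 were. The list was called higher by camera (adjusted p = 0.00239), but not with an estimated correlation (adjusted p = 0.508). The gap call (adjusted p = 0.0427) ended with library size alone (adjusted p = 0.0534) and without each library other than reference replicate 1 (0.0947 to 0.133). The pgk call ended without each deletion library (0.0563 to 0.0642), and the tpiA call without deletion replicates 1 and 2 (0.0541 and 0.0528). In the list of anaplerosis and the pyruvate node, where 3 of 8 genes were matched, ppc was the 1 gene called of 3, also adjusted over the list alone, and 2 were higher without reference replicate 1.

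In the list of oxidative and thiol stress 2 genes were higher. The mtr gene, which encodes mycothione reductase, rose from 229 ± 38 to 953 ± 38.7 CPM (SD, n = 3 each; log2 fold change 2.05, edgeR adjusted p = 0.00473). The gene for methionine sulfoxide reductase, msrA, rose from 639 ± 80.7 to 1654 ± 206 CPM (log2 fold change 1.37, edgeR adjusted p = 0.0122), a call that ended without each deletion library (0.0516 to 0.0734). These were 2 of 7 tested members; adjusted over the list alone 3 were higher, and without reference replicate 1 the count was 5. The list was called higher by camera (adjusted p = 0.00641), but not with an estimated correlation (adjusted p = 0.508). Here reference replicate 1 lay near the others, at 267 CPM of mtr against 230 and 191.

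Genes of nitrate respiration had the lowest median log2 fold change among the lists, -4.77. The subunit genes narH and narI of the respiratory nitrate reductase and the gene for its assembly chaperone, narJ, fell, with log2 fold changes of -4.88, -4.48 and -4.77. In their order on the minus strand, narH, narJ and narI, the fall did not grow downstream. All 3 tested members, of 6 genes fixed for the list, were lower, also adjusted over the list alone. The level of narH went from 1859 ± 1063 to 63.1 ± 8.6 CPM (SD, n = 3 each; edgeR adjusted p = 0.00411), with 901 CPM in reference replicate 1 against 3002 and 1674 in the other 2. Each of the 3 calls held without any 1 library. The list was called lower by camera (adjusted p = 0.00239), but not with an estimated correlation (adjusted p = 0.508).

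The tested genes of ATP synthase and some of the aerobic respiratory chain were lower. For ATP synthase all 4 tested genes, of 8 fixed for the list, fell, also adjusted over the list alone, with log2 fold changes of -3.09 for atpD, -3.04 for atpC, -2.61 for atpA and -1.54 for atpB. Along the plus strand their order is atpB, atpA, atpD and atpC. Neighbouring genes on a strand were paired where the gap was under 50 bp and both had at least 20 reads in every library. Over 891 such pairs, the downstream gene was lower against its upstream neighbour in the deletion strain, by a median difference of -0.23 on the log2 scale and in 64.1% of pairs (exact permutation p = 0.1 on the library medians, two-sided, the smallest that 3 against 3 allows). The level of atpD went from 2135 ± 1222 to 252 ± 82.2 CPM (SD, n = 3 each; edgeR adjusted p = 0.00902), with 736 CPM in reference replicate 1 against 2995 and 2673. In the respiratory chain qcrB, the cytochrome b subunit gene of the bc1 complex, fell by 2.71 and cydC, of the transporter needed for cytochrome bd assembly, fell by 2.57 on the log2 scale. These were 2 of 4 tested members, of 12 genes fixed for the list, and 4 were lower adjusted over the list alone or without reference replicate 1. Camera called both lists lower, at adjusted p of 0.0191 for ATP synthase and 0.0291 for the respiratory chain, but not with an estimated correlation (adjusted p = 0.508 for each). The atpA, atpC and atpD calls ended without deletion replicate 1 or 2 (0.055 to 0.0609), the atpB call without each library other than reference replicate 1 (0.0595 to 0.125), and the respiratory list's without reference replicate 3 (0.0622). The qcrB gene stood at 1270 CPM in reference replicate 1 against 3608 and 2525.

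All 4 tested genes of iron-sulfur cluster assembly, of 7 fixed for the list, were lower, also adjusted over the list alone, with log2 fold changes of -2.88 for sufC, -2.55 for sufD, -1.60 for sufB and -1.13 for sufU. Along the minus strand their order is sufB, sufD, sufC and sufU. The fall grew from sufB to sufD and sufC, but sufU, the last in that order, fell least. The median difference of downstream against upstream genes, given for ATP synthase, was -0.23 over all pairs. The sufC level went from 963 ± 564 to 131 ± 28.9 CPM (SD, n = 3 each; edgeR adjusted p = 0.00822), with 371 CPM in reference replicate 1 against 1494 and 1025. The list was called lower by camera (adjusted p = 0.0269), but not without reference replicate 3 (0.0622) or with an estimated correlation (adjusted p = 0.508). The sufC call ended without deletion replicate 1 or 2 (0.0548 and 0.0522), and the sufB, sufD and sufU calls without reference replicate 2 or any deletion library (0.0538 to 0.14), sufB also without reference replicate 3 (0.0738).

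In the list of aromatic and tryptophan synthesis, where 7 of 11 genes were matched, 7 of 7 tested members were lower, also adjusted over the list alone. Genes with an aro symbol, some of them outside the list, did not all fall. Of 9 tested, a grouping chosen after seeing the data, 1 was higher and 4 lower, with a median log2 fold change of -0.302. The tryptophan genes trpD, trpCF and trpA had log2 fold changes of -2.60, -2.17 and -1.86, and the shikimate kinase gene aroK had -1.77. The trpD level went from 146 ± 58.9 to 24.1 ± 5.51 CPM (SD, n = 3 each; edgeR adjusted p = 0.00473), with 101 CPM in reference replicate 1 against 213 and 126. The list was called lower by camera (adjusted p = 0.000825), but not with an estimated correlation (adjusted p = 0.508). The 4 named calls held without any 1 library.

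In the list of myo-inositol and gluconate catabolism 3 of 4 tested genes fell, also adjusted over the list alone, with log2 fold changes of -3.31 for iolG, -1.41 for iolD and -1.32 for iolB. All 4 were iol genes, of 11 genes fixed for the list. No gluconate gene was matched by symbol, so the list's results do not speak for gluconate catabolism. The iolG level went from 454 ± 132 to 45.9 ± 7.08 CPM (SD, n = 3 each; edgeR adjusted p = 0.00411), with 321 CPM in reference replicate 1 against 585 and 457. Camera called the list lower (adjusted p = 0.0285), but not with an estimated correlation (adjusted p = 0.508), with limma-voom and sample weights (0.0623), without reference replicate 1 (0.0601) or without reference replicate 3 (0.0761). The iolB call ended without reference replicate 3 or any deletion library (0.0558 to 0.12).

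**Figure D3:**
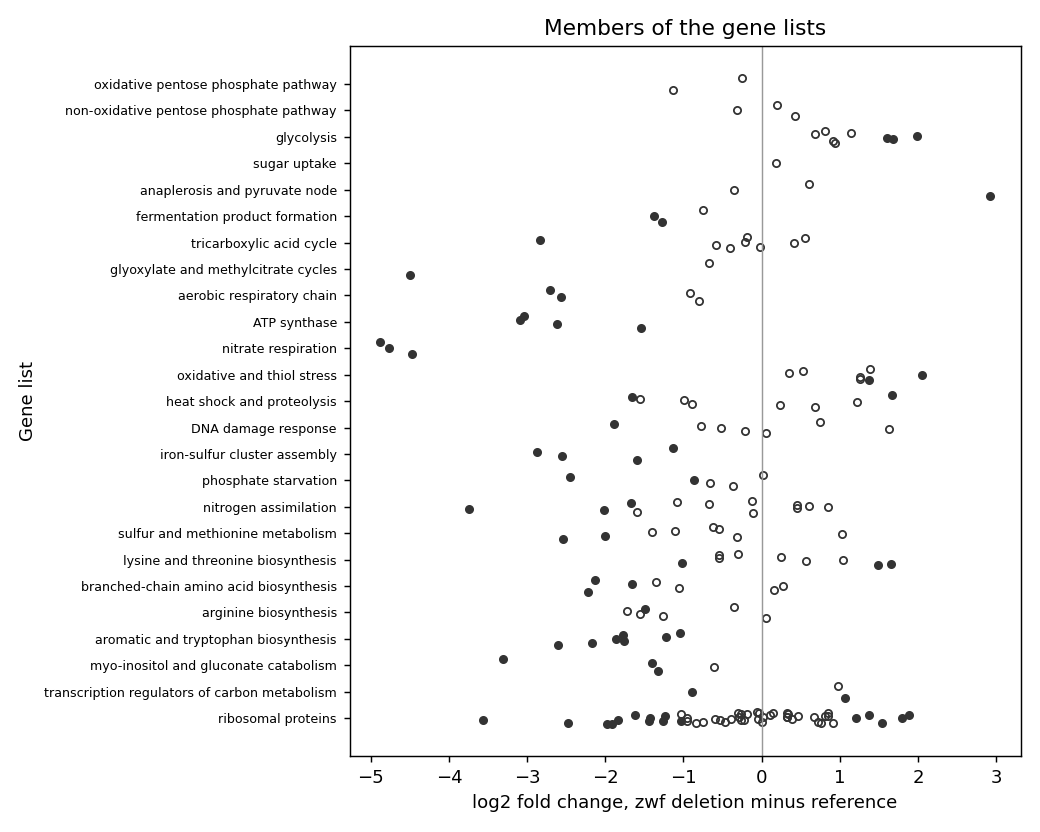
Log2 fold changes, zwf deletion minus reference, of the tested members of 25 gene lists, with zwf left out. Filled points passed an adjusted p of 0.05 over all genes and open points did not; the nitrate respiration genes lie between -4.88 and -4.48 and ppc at 2.92.

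Camera called none of the other 14 lists tested (adjusted p 0.141 to 0.990), though some of their genes changed. The lists of the oxidative pentose phosphate pathway, sugar uptake and the glyoxylate and methylcitrate cycles had too few members for that test. In central metabolism the isocitrate lyase gene aceA fell by 4.49 on the log2 scale (edgeR adjusted p = 0.00906), from 402 and 1050 CPM in reference replicates 2 and 3 and 86.2 CPM in replicate 1 to 22.7 ± 3.02 CPM (SD, n = 3), 1 of 2 tested glyoxylate genes, and both were lower without reference replicate 1; the call ended without deletion replicate 1 (0.0543). The methylcitrate genes of that list were not matched by symbol, so its counts leave them out. Of 3 rows with such a symbol, the last 2 of them chosen after their values were seen, prpB at NCgl0629 fell by 4.19, while prpD had 0.68 and prpB_NCgl0665 had 0.70, not called (adjusted p of 0.0573 and 0.0604). The succinate dehydrogenase gene sdhA fell by 2.83, 1 of 8 tested genes of the tricarboxylic acid cycle, and its call also ended without deletion replicate 1 (0.0515). In that cycle 2 genes were higher and 3 lower without reference replicate 1. The list named fermentation product formation had 4 of 10 genes matched, and its 3 tested members were pta, lldD and dld. Of these 2 were lower, lldD at -1.38 and pta (phosphate acetyltransferase) at -1.27, with the pta call lost without deletion replicate 1 (0.105) and 4 other libraries. That count does not speak for product formation as a whole. The lactate dehydrogenase gene ldh had 1 read in reference replicate 1 and 0 in the other 5 libraries, and 0 reads in a deletion library allow at most 0.17 to 0.192 CPM. Whether these strains carry an intact ldh is not given in the sources used here, and no fold change is given. In the sugar uptake list the single tested gene, ppgK (polyphosphate glucokinase), had 0.18 with adjusted p of 0.565.

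Some genes of nitrogen, sulfur and phosphate supply were lower. The glutamate synthase genes gltD and gltB had log2 fold changes of -3.74 and -2.02 and the urease accessory gene ureE had -1.67, 3 of 12 tested nitrogen genes. The sulfate adenylyltransferase gene cysD fell by 2.54 and the regulator gene ssuR fell from 75.5 ± 45.5 to 18.8 ± 1.57 CPM (SD, n = 3 each), 2 of 8 sulfur and methionine genes. The phosphate transporter genes pstB and pstA had -2.45 and -0.87, 2 of 5 phosphate genes. Adjusted over the list alone the lower counts were 4, 3 and 3, with 1 nitrogen and 1 sulfur gene higher. Without reference replicate 1 the nitrogen and the sulfur list each had 1 gene higher and 6 lower. Without reference replicate 3 the nitrogen list had 2 higher and 1 lower, and without any 1 deletion library the sulfur list had 0 called. The gltD and pstB calls held without any 1 library, while those of the other 5 genes ended without deletion replicate 1 (0.0652 to 0.145) among others.

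Amino acid genes outside the tryptophan pathway were split. In lysine synthesis dapB and dapA rose by 1.65 and 1.49 while dapD fell by 1.02, of 9 tested genes of the lysine and threonine list. Branched-chain genes ilvN, leuD and leuA had -2.23, -2.14 and -1.66, 3 of 7 tested. Of 6 arginine genes argF was lower, at 172 ± 92.8 CPM in the reference and 60.7 ± 6.6 CPM in the deletion strain (SD, n = 3 each). Without reference replicate 1, 5 of the 6 arginine genes were lower, while without reference replicate 3 the counts were 1 higher and 0 lower and the median log2 fold change was -0.23 in place of -1.38. Without any 1 of the other libraries 0 arginine genes were called. The lysine and threonine counts were 4 higher and 3 lower, and the branched-chain count 5 lower, without reference replicate 1. Adjusted over the list alone the lysine and threonine counts were 2 higher and 1 lower, the branched-chain count was 4 lower and the arginine count 0. The dapB call held without any 1 library, and those of the other 6 genes ended without deletion replicate 1 (0.054 to 0.137) among others.

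Chaperone, repair, regulator and ribosomal genes did not move in a single direction. The disaggregase gene clpB rose by 1.66 and the chaperonin gene groEL_2 fell by 1.66, of 8 heat shock genes, where 2 were higher and 3 lower adjusted over the list alone. The DNA polymerase gene dnaE2 fell by 1.89, the 1 call among 7 DNA damage genes under both adjustments. Of 3 carbon regulators ramA rose by 1.07 and ramB fell by 0.89, with 2 higher and 1 lower adjusted over the list alone. Of 51 ribosomal protein genes 5 were higher and 11 lower, and 6 and 12 adjusted over the list alone. The log2 fold change was -3.57 for rpsQ, -2.47 for rplL, -1.98 for rplK and -1.92 for rplA. Without reference replicate 3 it was -1.18 for rplK and -1.20 for rplA. The direction of the ribosomal balance depended on single libraries. Without reference replicate 1, 7 were higher and 25 lower; without reference replicate 3, 8 were higher and 6 lower, with a median log2 fold change of 0.25 in place of -0.19. The counts were 2 and 4 without reference replicate 2, and 2 and 2, 2 and 2, and 2 and 3 without deletion replicate 1, 2 or 3. In 25 of 26 pairs of neighbouring ribosomal genes the downstream gene was lower against its upstream neighbour in the deletion strain, with a median difference of -0.371. Neighbouring pairs can share a gene, so the 26 pairs are not independent. The heat shock counts were 3 higher and 4 lower without reference replicate 1, those of DNA damage genes 2 and 3, and those of carbon regulators 2 and 1. The dnaE2, rpsQ and rplL calls held without any 1 library, and those of the other 6 named genes ended without deletion replicate 1 (0.0836 to 0.135) among others.

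Other large rises were in secE, cmr and genes with no symbol. NCgl1289 rose by 2.80, secE (a subunit of the protein translocase) by 2.57, NCgl2742 by 2.53, NCgl0429 by 2.52, NCgl2252 and the drug exporter gene cmr by 2.43, NCgl2294 by 2.42, NCgl1318 by 2.41 and NCgl0171 by 2.34 on the log2 scale. The secE, cmr and NCgl2742 calls ended without deletion replicate 1 (0.0569 to 0.0715) among others. For some of these genes reference replicate 1 stood above reference replicates 2 and 3, with 255 CPM of secE against 95.7 and 56.8. For cmr it had 324 CPM against 80.3 and 105. For NCgl2252 it was the lowest, with 332 CPM against 450 and 753. NCgl1318 stood at 83 ± 10.9 CPM in the reference and 442 ± 40.8 CPM in the deletion strain (SD, n = 3 each; edgeR adjusted p = 0.00411). Other large falls had log2 fold changes of -4.34 for NCgl0123, -4.01 for NCgl0298 and -3.95 for NCgl0204. NCgl2748 had 258, 68.2 and 167 CPM in the reference replicates and 0 in the deletion libraries, but 100% of its reads were shared with other places, so its value is uncertain. Of the 68 named genes called, 50 and 56 were called without reference replicate 2 or 3, and 32, 35 and 44 without deletion replicate 1, 2 or 3.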

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

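The alternatives with unique reads only, thinned deletion libraries, a subtracted floor and sample weights were chosen after seeing the data; the others were fixed before. The zwf loss was called under every setting tried, with log2 fold changes from -13.15 with the floor subtracted to -10.23 without zwf deletion replicate 3. The higher count moved from 276 to 487 with DESeq2, and the higher and lower counts moved to 28 and 158 against a 2-fold change and to 818 and 867 with sample weights. Leaving out 1 library gave 62 to 926 higher and 167 to 965 lower genes. The replicate number used as a block gave 301 and 461, with correlations of same-numbered deviations of 0.095, 0.039 and -0.07. Those between different numbers ran from -0.122 to 0.108. No pairing by number was seen, but with 3 libraries per strain a shared day or batch cannot be excluded. Of the 4 neighbours of zwf 1 was called with DESeq2, upper-quartile factors or library size alone, 3 with sample weights, and 0 to 3 with 1 library left out. Of the 68 named genes called, 34 passed against a 2-fold change, and 32 to 68 with 1 library left out. The 8 gene lists called became 0 with an estimated correlation, where camera gave 1 list an unadjusted p under 0.05, 13 with fry, which does not compare a list with other genes, and 5 to 8 with 1 library left out, where 5 was without reference replicate 3. For genes not called in either setting, ppgK turned from 0.18 to -0.003 with library size alone, and gndA ranged from -0.40 to 0.047 with 1 library left out, turning without reference replicate 1. The smaller counts against a 2-fold change follow from that test's construction, and fewer libraries were used where 1 was left out, which does not account for the larger counts without reference replicate 1; for these and the other shifts the cause was not tested. Removal of ribosomal and transfer RNA rows was not run, since no matched row is one. Reference depth limits what can be seen of genes under about 1.45 CPM.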

Other observations

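Tests on the swapped label, the mixture, the spread added by reference replicate 1 and the count of genes over splits were chosen after their results had been seen, as were the genes named below. In 10 splits of the 6 libraries into 3 and 3, the real split called 851 genes and the highest other 0 with edgeR, with 1257 and at most 202 at an unadjusted p under 0.05, and 1 split reached the real count. The same splits called 8 gene lists in the real split and 9 in the highest other, and 4 splits reached the real count; those with reference replicate 1 beside 2 deletion libraries called 8 or 9, which points to a structure of the samples. With 10 splits the share cannot fall under 0.1, too few to reach 0.05.

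Along the ribosomal protein cluster that begins with rpsJ, the log2 fold change was 0.92 for rpsJ and 0.72 for rplC, neither called, and rpsQ, further downstream, fell by 3.57. NCgl2809, which lies next to ldh, had 42499 reads in reference replicate 1, 9026 CPM, against 957 and 434 CPM in the other reference libraries and 1134 ± 104 CPM (SD, n = 3) in the deletion strain. Among 46 groups of genes that share a symbol stem, a grouping chosen after seeing the data, camera called 0 with the preset and 0 with an estimated correlation, where 12 and 0 had an unadjusted p under 0.05. No read was assigned to 5 genes, NCgl0236, NCgl0868, NCgl1663, NCgl1772 and NCgl2297, in any library.

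More genes were lower than higher, and among the 597 least abundant genes 143 were lower and 20 higher, against 66 and 98 among the 597 most abundant. The excess depended on the test, with a ratio of lower to higher calls of 2.08 with edgeR, 1.42 with DESeq2, 1.06 with sample weights and 5.64 against a 2-fold change. In edgeR, subtracting a floor left the ratio at 2.14, against DNA carry-over as the whole cause, though a larger floor was not tried, and thinning the deletion libraries left it at 2.27, against depth as the whole cause. The excess depended on reference replicate 1. Without that library the ratio was 1.04, and both directions gained calls, from 276 to 926 higher and from 575 to 965 lower. With sample weights, at 1.06, that library had a weight of 0.0976 against 0.516 to 3.13 in the others. Whether its spread made the excess was not decided, since the test asked for fewer lower calls. A library that adds spread hides calls in both directions, so its removal could hardly give fewer. A biological difference between the strains stays open and untested.

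Reference replicate 1 lay between the other reference libraries and the deletion libraries on the first principal component. On the second, 17.1% of the variance, it lay at 34.9, outside the other libraries, which ran from -13 to -0.9. A swapped label is argued against by the 199 zwf reads of reference replicate 1. Greater depth is argued against by a mean correlation across genes of 0.912 with the deletion libraries after thinning, against 0.873 and 0.835 with the other reference libraries. A mixture with deletion-strain RNA cannot be told apart from a different state of the culture, since 4.32% of genes lay over 2-fold outside the other libraries, between the bounds of 1% and 5% set for that test, and reference replicate 3 had 4.05%. No biological explanation was tested.

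The 891 pairs of neighbouring genes on a strand had a gap under 50 bp and at least 20 reads per gene in every library. In these pairs the downstream gene was lower against its upstream neighbour in the deletion strain, with a median difference of -0.23 on the log2 scale and 64.1% of pairs below 0. The exact permutation test on the library medians gave p = 0.1, two-sided, the smallest that 3 against 3 allows. Depth is argued against by a median difference of -0.214 after thinning. Compression of low levels in the reference cannot be told apart from a real shift, since pairs whose downstream gene is the more abundant had -0.062, between the bounds of 0 and -0.1 set for that test. A difference in transcription or decay along operons between the strains stays open, and RNA integrity was not tested.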
